A study of Sus scrofa with 21 samples.

How the data were processed

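Gene expression was measured on 2-colour oligonucleotide arrays in PSPA cells, a pig cell line of subcutaneous preadipocytes, the precursor cells that can turn into fat cells. Per the labels' protocols, total RNA (400 ng per labelling) was amplified into dye-labelled cRNA, and on each of the 21 arrays the RNA of differentiating cells carried the red dye Cy5 and the RNA of undifferentiated control cells the green dye Cy3. The labels record no array with the dyes exchanged, so a difference between the dyes that is constant for a probe cannot be separated from a difference between differentiating and control cells; it cancels in comparisons between times. The 21 arrays fall into 7 times after induction (1 h, 2 h, 3 h, 4 h, 12 h, 48 h and 6 d) with 3 replicates each, which the labels call biological, so that p-values measure the spread between these samples. Groups and replicate numbers were taken from the sample titles. The titles, the source names and the time characteristic give the same time for every sample, but the description field gives the next later time for the first 6 times and 1 h for the 6 d samples, and it numbers 1 of the 6 d samples differently. The titles were followed throughout.

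The authors deposited 1 table of log10 ratios, with 27476 numbered probes and 1 column per array. Per the submitters' processing notes, Agilent Feature Extraction was used; its version, the array design, the normalization and the rule that left values blank are not given in the sources used here. The direction, differentiating over undifferentiated cells, follows from the dyes in the labels' protocols and from the wording of the descriptions. The base of the logarithm is stated in no source. It was taken as 10, the base in which this scanner software writes its log ratio, and every fold printed rests on that: the highest value, 2.76, is a 577-fold ratio in base 10 and a 6.78-fold ratio in base 2. Tests and counts of calls at an adjusted p do not depend on the base. The array medians of the deposited log10 ratios lay between -0.0366 and 0.00617, and no value was exactly 0; how they were centred is not given in the sources used here. Each array held between 15446 and 18550 values. A value was present on all 21 arrays for 14780 probes, on some arrays for 6461 probes and on none for 6235 probes. No scanner intensities were used here, so signal over background is unknown, and precision is limited by the number of arrays.

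The probe numbers are not paired with genes in the table, and 0 of them matched an identifier in the reference tables of pig genes. Results are therefore given per probe, and the gene lists fixed before the data were examined could not be tested. Several probes may report the same gene. The rule for named items, also fixed beforehand, would have named the largest changes of each comparison. Because a probe number carries no gene name, only the probe with the largest rise and the one with the largest fall at 1 h and at 6 d, among those past the threshold with the same sign on all 3 arrays, are named here.

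Values were used as deposited, for the 14780 probes measured on all arrays. Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per time and all 21 arrays sharing 1 estimate of the spread (14 residual and 3.13 prior degrees of freedom). Each time was tested against 0, which is the comparison with the control RNA on the same array. Where the control RNA was shared between arrays, its own variation is only partly in the error. The intervals 1 h to 4 h, 4 h to 12 h, 12 h to 48 h and 48 h to 6 d were tested as contrasts, and a moderated F test asked whether the 7 times differed. All tests were two-sided with Benjamini-Hochberg adjustment over all probes within a comparison and a threshold of 0.05. No undifferentiated sample is recorded as kept in culture for the same length of time, so time in culture and medium cannot be separated from differentiation here.

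Replicate numbers were taken to pair the arrays, because the design text describes the whole set of times as carried out 3 times. After removal of time means, arrays with the same number and different times correlated with a mean r of 0.542 in set 1, 0.432 in set 2 and 0.248 in set 3 (lowest pair -0.0978, 14 of 21 pairs over 0.1), and all 21 arrays correlated best with an array of their own number. Removal of time means forces correlations between sets below 0 where those within sets lie above it, so they are no separate evidence. The planned main model had no block. The alternative with the number as a fixed block takes the variation of the control between sets out of the error of a comparison with the control, so its p-values there are too small. A random block (correlation within a set 0.326), added after the data were seen, does not have this property. Comparisons that share control RNA were also simulated 20 times with no effect, with that correlation within sets.

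The tests were checked on simulated data for the 14780 probes, with their real spread, 0.3 of the variance shared within sets and 200 probes changed at 6 d. For the comparison at 6 d, 14.9% of probes changed by 0.1 on the log10 scale were recovered, 64.2% of those changed by 0.2 and 90.9% of those changed by 0.4, with 10 false calls. For the interval 48 h to 6 d the shares were 1.49%, 44.8% and 75.8%, with 2 false calls. For the F test they were 0%, 26.9% and 65.2%, with 0 false calls. Far fewer probes were changed here than the 7803 called at 6 d in the real data. The Benjamini-Hochberg cutoff depends on the share of changed probes, so these shares and false calls do not carry over to the real counts.

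Alternatives were median centring of each array, quantile normalization between arrays, the replicate block, keeping probes with at least 2 values at each time, fitting only the times compared, robust moderation, an added 2-fold minimum, and leaving out each replicate set or array. Leaving out probes at exactly 0 would have removed none, testing each probe by itself is what was done, and the median over the probes of a gene and the alternatives for gene lists need gene names, so these were not run.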

Results

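The series followed gene expression while porcine preadipocytes of the PSPA line were induced to become adipocytes. Confluent cultures were switched to a medium rich in glucose (4.5 g/L) and supplemented with fetal bovine serum (10%), octanoate at 5 mM, biotin at 33 μM, pantothenate at 17 μM, dexamethasone at 0.25 μM and insulin at 5 μg/mL. Dexamethasone is a synthetic glucocorticoid, pantothenate a precursor of coenzyme A and octanoate a medium-chain fatty acid. RNA was taken at 1 h, 2 h, 3 h, 4 h, 12 h, 48 h and 6 d and compared on the same array with RNA of undifferentiated cells, with 3 biological replicates per time and 21 arrays in all. The arrays carried 27476 numbered probes, of which 14780 had a value on all arrays and were tested. Values are log10 ratios to the undifferentiated cells, and folds take the base as 10, which no source states. The median SD between the 3 replicates of a time ranged from 0.0455 at 1 h to 0.0742 at 6 d.

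Profiles close in the order of the times resembled each other, and those of 48 h and 6 d shared little with those of 1 h and 2 h. Averaged over arrays of different replicate sets, the correlation across the 14780 probes was 0.536 between 1 h and 2 h, 0.67 between 3 h and 4 h, 0.626 between 4 h and 12 h, 0.382 between 12 h and 48 h, and 0.694 between 48 h and 6 d. Between 1 h and 6 d it was -0.0429, but 4 h reached 0.197 with 48 h and 0.165 with 6 d. The lowest correlation between any pair of arrays was -0.296, between a 1 h and a 6 d array. Probes are not independent replicates, so these values carry no p. Within replicate sets the corresponding means were higher, 0.69 for 1 h with 2 h, 0.809 for 48 h with 6 d and 0.0123 for 1 h with 6 d. Unchanged cells simulated against shared controls gave a correlation of 0.328 between the means of 1 h and 2 h, where 0.766 was observed, and of 0.331 between those of 1 h and 6 d, where -0.0536 was observed. The covariance exceeded the simulated one by 0.00974 for 1 h with 2 h and by 0.0356 for 48 h with 6 d, and lay below it for 1 h with 6 d (difference -0.00233). The simulation held no constant dye difference and no control RNA common to all sets. Either would also raise the covariance, so the excess does not separate them from shared changes in expression. Replicates of a time correlated with a mean r between 0.635 at 3 h and 0.85 at 12 h. The first principal component, with 46.4% of the variance, separated all 48 h and 6 d arrays (scores of at least 13.3) from all others (scores of at most 0.924).

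**Figure D1:**
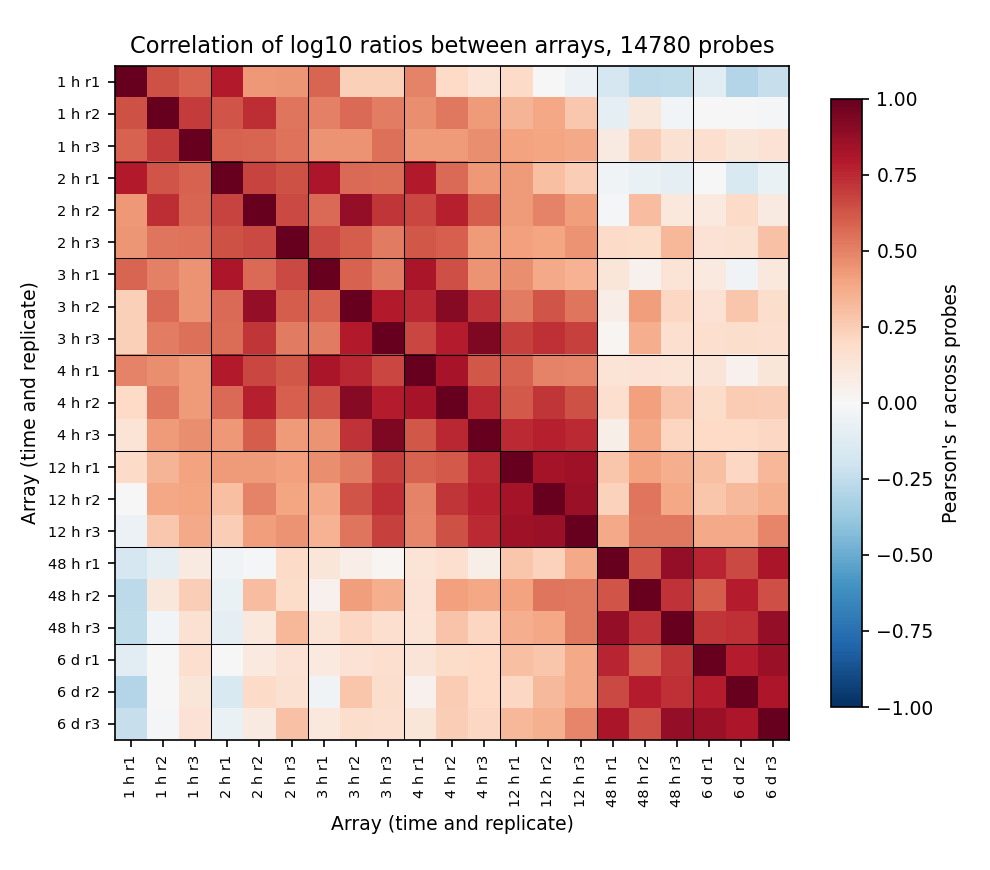
Pearson's r across 14780 probes between the log10 ratios of all 21 arrays, ordered by time and replicate (r1 to r3) on both axes, with colour from -1 to 1. Correlation tends to fall with distance in the order of the times, not in hours. The mean between sets for 12 h is 0.626 with 4 h, 0.382 with 48 h and 0.226 with 1 h. The lowest value, between a 1 h and a 6 d array, is -0.296.

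The first hours after induction were asked about with 4 closely spaced times. Already at 1 h, 669 probes were higher and 485 lower than in undifferentiated cells (limma, adjusted p under 0.05), and the changed group grew to 1719 higher and 1483 lower at 2 h, 2757 and 2470 at 3 h, and 3043 and 2911 at 4 h. Most of these changes were small: the median size among called probes was 0.191 at 1 h (1.55-fold) and 0.173 at 4 h (1.49-fold), with a median standard error of 0.0409. At least 2-fold changes were made by 155 higher and 93 lower probes at 1 h and by 500 higher and 474 lower probes at 4 h. The probe with the largest rise at 1 h, probe 12293, was at 1.32 ± 0.399 at 1 h (SD, n = 3), a 20.9-fold level (adjusted p = 5.65e-05) that was 13.3-fold without replicate 2 and 33.3-fold without replicate 3. It stood at 1.66 ± 0.119 at 2 h and 0.979 ± 0.573 at 4 h, fell by 1.44 between 4 h and 12 h (SE 0.234, adjusted p = 0.00349), and was below the control at 48 h, at -0.962 ± 0.104 (adjusted p = 0.000238). The probe with the largest fall at 1 h, probe 2769, was at -0.98 ± 0.364, 9.55-fold lower (adjusted p = 0.000457) and 5.93-fold lower without replicate 2. It was past the threshold at all 7 times and stood at -0.498 ± 0.176 at 6 d (adjusted p = 0.0118). With the fixed replicate block, whose p-values are too small against the control, 2678 probes were called at 1 h and 5222 at 2 h, and with the random block 1230 and 3377. With quantile normalization 4967 and 4930 were called, and the share of higher calls was 44.3% at 1 h, 47.4% at 2 h, 47.5% at 3 h and 47.8% at 4 h, against 58%, 53.7%, 52.7% and 51.1% as deposited. These shares were 49.3%, 48.1%, 49.4% and 48.5% with the fixed block and 63.6%, 60.2%, 53.3% and 55.1% with median centring, so neither direction prevailed under all settings. Fitted on the 3 arrays of the time alone, 1993 probes were called at 2 h and 2204 at 3 h. The counts fell to 530 and 404 at 1 h without replicate 1 or 2 of that time, to 1963 at 2 h without its replicate 2, to 3468 at 3 h without its replicate 2 and to 3485 at 4 h without its replicate 2.

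At 12 h, 3449 probes were higher and 3803 lower, 49.1% of those tested, and with each array centred on its median 3778 were higher and 3291 lower. The median size of a called change was still 0.175 (1.5-fold), and 622 higher and 606 lower probes differed at least 2-fold. Probe 24497, which had been at -0.0991 ± 0.108 at 1 h (adjusted p = 0.826), was at -1.42 ± 0.259 at 12 h, 26.4-fold lower (adjusted p = 3.58e-05). Without replicate 2 of 12 h, 4194 probes were called.

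The late stage was covered by 48 h and 6 d. At 48 h, 2765 probes were higher and 3343 lower, and at 6 d, 2876 were higher and 4927 lower, 52.8% of those tested. Fitted on the 3 arrays of the time alone, 3639 probes were called at 48 h and 4775 at 6 d. The largest rises came at 6 d: 67 probes were at least 10-fold higher there, against 11 at 48 h and 4 at 1 h, and 11 probes were at least 10-fold lower, against 8 at 48 h and 0 at 1 h. The top hundredth of probes began at 5.24-fold at 6 d and 3.23-fold at 48 h. Probe 10372 was at 2.58 ± 0.0956 at 6 d (SD, n = 3), a 384-fold level (adjusted p = 3.41e-12) that was 53.1-fold with quantile normalization. It had been at -0.00328 ± 0.109 at 12 h (adjusted p = 0.978) and 0.57 ± 0.119 at 48 h (adjusted p = 7.04e-05), so that it rose 103-fold between 48 h and 6 d (log10 difference 2.02, SE 0.12, adjusted p = 2.68e-08). Probe 24497 was at -1.87 ± 0.296 at 6 d, 74.7-fold lower than in undifferentiated cells (adjusted p = 9.47e-07) and 25.6-fold lower with quantile normalization. The excess of lower over higher probes at 6 d depended on centring. The median of all probes was -0.0311 there, and with each array centred on its median, which moved array medians by up to 0.0363, 3841 probes were higher and 3829 lower. At 48 h, 4049 probes were called without replicate 3 of that time.

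**Figure D2:**
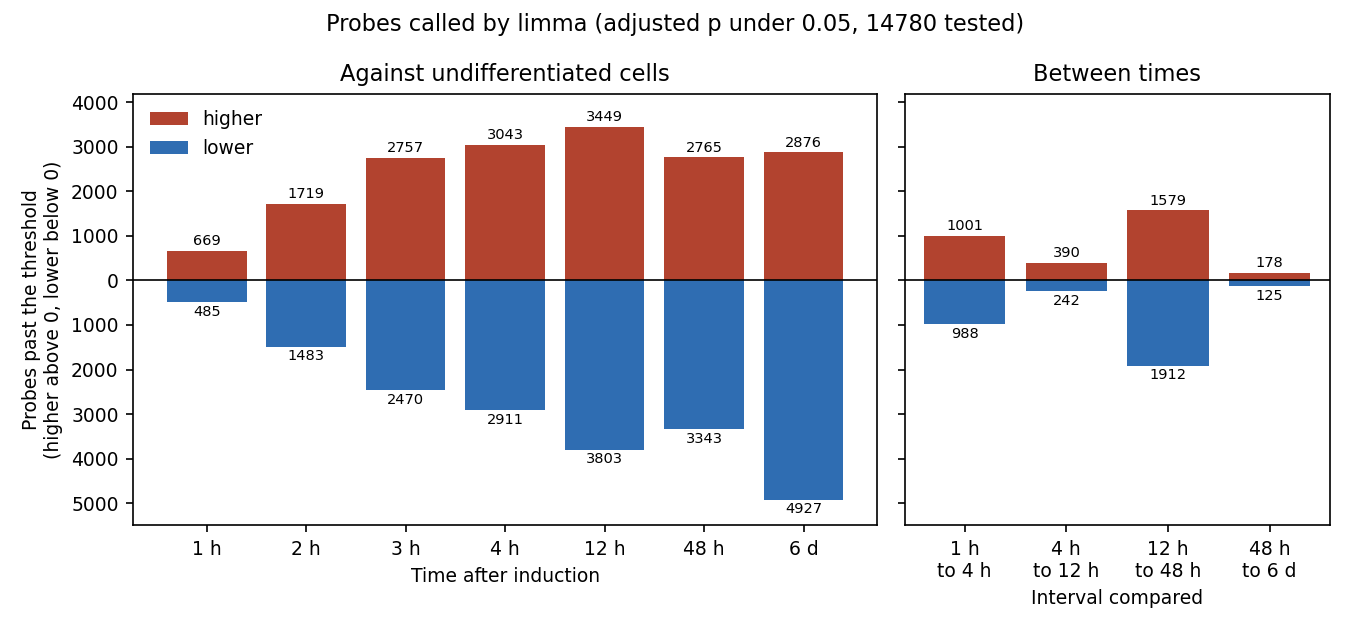
Number of probes past the limma threshold (adjusted p under 0.05) on the vertical axis, higher above 0 and lower below 0, for each time against undifferentiated cells (left, 3 arrays per time) and for 4 intervals between times (right). The count of lower probes is 485 at 1 h, 3803 at 12 h, 3343 at 48 h and 4927 at 6 d. With each array centred on its median, which is not drawn, it is 3829 at 6 d. The 12 h to 48 h interval has the most calls on the right.

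Comparisons between times, in which a constant dye difference cancels, asked when expression changed most. From 1 h to 4 h, 1001 probes rose and 988 fell, and from 12 h to 48 h, 1579 rose and 1912 fell. Fewer were called from 4 h to 12 h, with 390 up and 242 down, and from 48 h to 6 d, with 178 up and 125 down. Of the probes called from 12 h to 48 h, 396 rose and 705 fell at least 2-fold, and from 48 h to 6 d, 113 rose and 27 fell at least 2-fold. These intervals differ in length. Fitted on its own 6 arrays, the interval from 4 h to 12 h gave 0 calls by limma (2933 at an unadjusted p under 0.05) and that from 48 h to 6 d gave 20. The main fit and the fit on 6 arrays both ignored the pairing by set. Differences between sets then stay in the error of an interval and can lower its count. With the replicate block, which removes differences between sets, the counts were 3797, 2589, 5767 and 1201 in the order of the intervals. With a random block they were 3614, 2356, 5540 and 1039.

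The direction of the last interval was not settled. From 48 h to 6 d, higher probes made up 58.7% of calls, 81.6% with median centring and 83.9% with quantile normalization, but 39.6% with the replicate block and 42.1% with the random block. All 4 counts also moved with single arrays. From 1 h to 4 h, 698 probes were called without 4 h replicate 2, 954, 1285 and 1288 without 1 h replicates 1, 2 and 3. From 4 h to 12 h, the count was 153, 145 and 1024 without 4 h replicates 1, 2 and 3, and 203 and 165 without 12 h replicates 2 and 3. From 12 h to 48 h it was 1887 without 12 h replicate 2. From 48 h to 6 d it was 150 without 48 h replicate 2, and 173 and 131 without 6 d replicates 2 and 3.

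Over the whole course, 8693 of the 14780 probes differed among the 7 times (moderated F test, adjusted p under 0.05), and 5030 and 4406 did without replicate set 2 or 3. Of the 8693, 2698 (31%) were farthest from the undifferentiated level between 1 h and 4 h, 1808 (20.8%) at 12 h and 4187 (48.2%) at 48 h or 6 d. Among probes with their extreme at 12 h, 1020 were higher and 788 lower, and among those with their extreme at 6 d, 1254 were higher and 1862 lower. The latter balance turned with median centring, to 1729 higher and 1280 lower at 6 d. A group of 2271 probes was called at no time. Another 192 were called in the same direction at all 7 times, 72 higher and 120 lower. Of these, 99 did not pass the F test for a difference among times and had a median size of 0.242 (1.74-fold). Not passing does not show that they were constant, and with the replicate block the F test called 11011 probes. For these 99, no dye exchange separates a constant dye difference from a constant difference in expression.

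The later course of early-called probes and the earlier course of late-called ones were also followed. To follow each group without choosing and measuring it on the same arrays, calls were made on 2 replicate sets and the median log10 ratio was read from the set left out, 3 times in turn. Probes called higher at 1 h (197 to 391 probes) stood at 0.256 ± 0.0787 at 1 h (SD over 3 sets), 0.303 ± 0.0235 at 2 h and 0.188 ± 0.0616 at 4 h. Their median was -0.015 ± 0.0218 at 48 h and -0.0396 ± 0.0305 at 6 d. A median near 0 does not mean that each probe returned. Of the 669 called higher at 1 h on all 3 sets, 135 were called higher and 241 lower at 6 d. Probes called lower at 1 h (169 to 214 probes) stood at -0.251 ± 0.0514 at 1 h and were still at -0.105 ± 0.044 at 6 d, below 0 in 3 of 3 sets. Probes called higher at 12 h went from 0.0251 ± 0.028 at 1 h to 0.192 ± 0.0587 at 12 h and 0.0375 ± 0.0195 at 6 d. Those called lower at 12 h went from -0.0392 ± 0.0277 at 1 h to -0.197 ± 0.0692 at 12 h and -0.125 ± 0.0278 at 6 d. The median of probes called higher at 6 d lay near 0 through 4 h (0.00498 ± 0.0207 at 4 h). It was then 0.0584 ± 0.0234 at 12 h, 0.147 ± 0.0317 at 48 h and 0.204 ± 0.0655 at 6 d. Single probes differed: of the 2876 called higher at 6 d on all 3 sets, 725 were called higher and 438 lower at 4 h. Probes called lower at 6 d stood at -0.0397 ± 0.0235 at 4 h, below 0 in 3 of 3 sets, and at -0.2 ± 0.0475 at 6 d. With 3 sets no exact test of these medians can reach 0.05. The set left out carries its dyes the same way as the others, so a constant dye difference stays in these medians. The array medians at 6 d themselves lay below 0, at -0.0206, -0.0366 and -0.0322 in sets 1, 2 and 3.

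**Figure D3:**
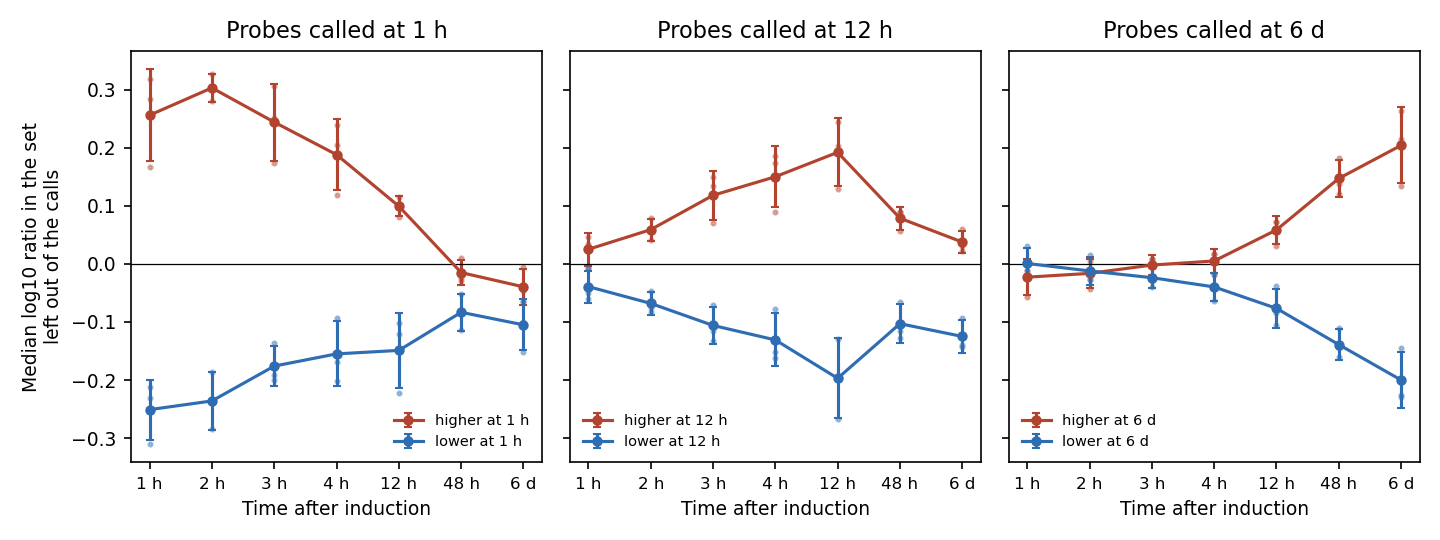
Median log10 ratio to undifferentiated cells (vertical axis) at each time (horizontal axis, not to scale) of probes called higher or lower at 1 h, 12 h and 6 d, measured in the replicate set left out of the calls. Lines and bars give the mean and SD over 3 left-out sets and small points the single sets. The median of the probes higher at 1 h is -0.015 at 48 h, while that of the probes higher at 6 d is 0.204 at 6 d. Single probes may lie on either side of these medians.

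Calls were compared between pairs of times. At 1 h and 6 d, 135 probes were higher at both times, against 130.2 expected of independent lists, 241 higher at 1 h and lower at 6 d (223 expected), 73 lower and then higher (94.4 expected) and 224 lower at both (161.7 expected). From 12 h to 48 h, 303 probes called higher at 12 h were called lower at 48 h and 190 did the opposite (780.1 and 711.5 expected). At both times, 1485 were higher and 1646 lower (645.2 and 860.2 expected). At 48 h and 6 d, 1936 were higher and 3018 lower at both (538 and 1114.4 expected). Direction changed for 7 from higher to lower and for 11 from lower to higher (921.7 and 650.5 expected). With no effect, simulated comparisons sharing controls gave at most 0.05 shared calls on average, a value that does not measure how far shared controls raise the overlap of longer lists. The controls could not be split, and part of the excess may come from shared control RNA. A constant dye difference would also put a probe on both lists in the same direction, and no dye exchange separates it. The 224 probes lower at 1 h and 6 d include the 120 called lower at all 7 times, of which 71 did not pass the F test for a difference among times.

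**Figure D4:**
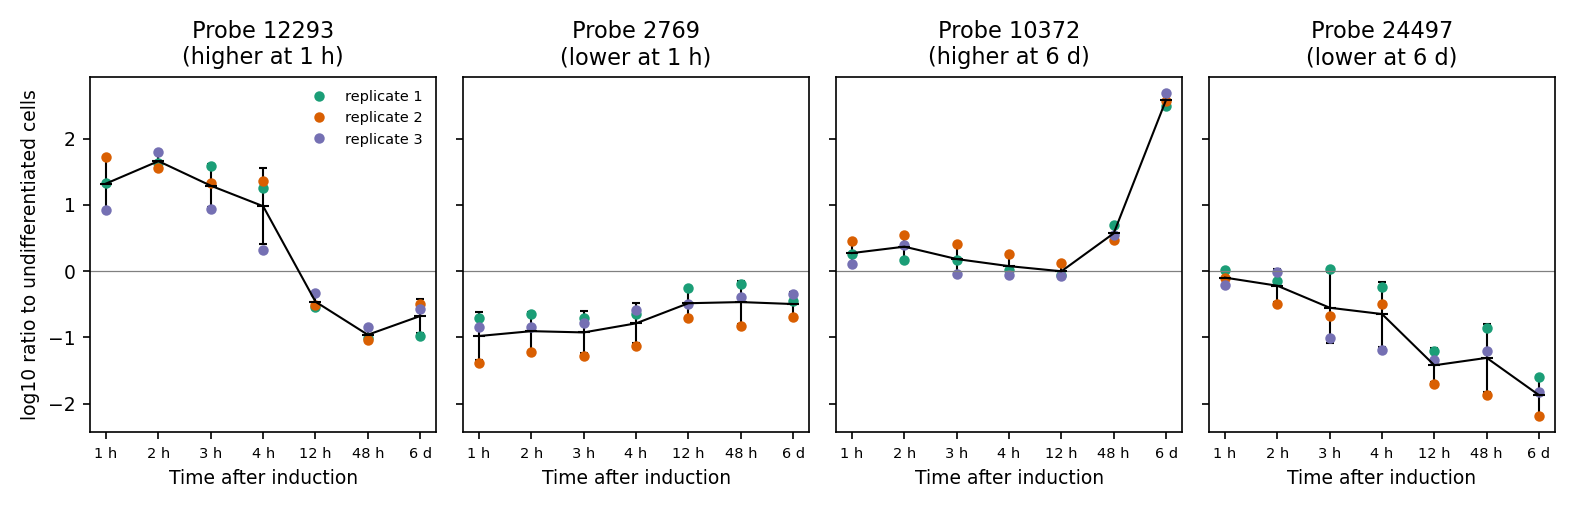
log10 ratio to undifferentiated cells (vertical axis) at each time (horizontal axis, not to scale) of the probes with the largest rise and fall at 1 h and at 6 d. Coloured points are the 3 replicates and lines with bars the mean and SD. Probe 12293 crosses from 1.32 at 1 h to -0.962 at 48 h, and probe 10372 rises from 0.57 at 48 h to 2.58 at 6 d.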

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

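The median tested here was known before that test was written; the first regrouping of the blanks was planned without its result, and the regrouping within replicate sets was added later. Among the probes without a full set of values, 18 were blank on all 12 arrays from 1 h to 4 h yet measured on all 3 arrays at 6 d. They draw attention because the comparisons between times used only probes measured on all arrays. Their log10 ratios at 6 d had a median of 1.37 (23.2-fold in base 10; range 0.0993 to 1.97), 17 of the 18 were above 0 on all 3 arrays, and 16 were at least 10-fold higher. None was measured at 12 h and 8 were measured on at least 1 array at 48 h. In the opposite direction, 6 probes were measured on all 12 early arrays and blank at 6 d.

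Generally better detection on the 6 d arrays would lift both dyes and leave ratios near 0, but the median of 1.37 lay above the central 95% of medians of 10000 equal draws from the 1987 incompletely measured probes with 3 values at 6 d (-0.0969 to 0.0905). Blanks falling at random among arrays are argued against: 2 of 100 regroupings of the arrays, the real one included, gave as many such probes. These regroupings ignored the replicate sets, and 1 of them gave 34, so blanks do follow some structure of the arrays. With times regrouped only within sets, the highest other of 100 gave 3. What stays open is that the rule behind the blanks is unknown and that a probe blank in the control has a ratio set by background. The hypothesis is that these transcripts may become detectable only late in differentiation. Among the 1987 incompletely measured probes with 3 values at 6 d, 71 were at least 10-fold higher there, against 67 of the 14780 fully measured ones. The counts of strong late rises above may therefore be too low. This stays open, since the 71 were not tested and some of their ratios may be set by background.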

How the results depend on the processing

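The 4 named probes stayed past the threshold in limma under all 24 alternative values (highest adjusted p 0.0323). Neither this nor their directions say much. They were chosen on the same arrays as the largest changes past the threshold with the same sign on all 3 arrays. The block also leaves the estimate as it is. Choosing extremes tends to overstate sizes at the time of choice. Sizes moved: quantile normalization took probe 10372 from 384-fold to 53.1-fold and probe 24497 from 74.7-fold to 25.6-fold lower, and leaving out replicate 2 took probe 12293 to 13.3-fold and probe 2769 to 5.93-fold lower. Counts stayed within 1.5 times under median centring, robust moderation, keeping probes with at least 2 values at each time (16373 probes) and, added after the data were seen, keeping probes measured on all arrays of the times compared. Quantile normalization, which gives every array the same spread, raised the count at 1 h from 1154 to 4967 and at 2 h to 4930, and lowered 48 h to 6 d from 303 to 62; it made 44.3% of the 1 h calls higher, against 58% as deposited. The replicate block raised 1 h to 2678, 2 h to 5222, and the intervals to 3797 (1 h to 4 h), 2589 (4 h to 12 h), 5767 (12 h to 48 h) and 1201 (48 h to 6 d), and all 1154, 1989, 632, 3491 and 303 probes called without it at 1 h and in the 4 intervals were among them; the random replicate block, added later, gave 3614, 2356, 5540 and 1039 for the intervals but 1230 at 1 h and 3377 at 2 h. Neither block changed any other count by over 1.5 times. Fitting only the times compared, with fewer degrees of freedom, gave 1993 at 2 h, 2204 at 3 h, 3639 at 48 h, 4775 at 6 d, 2208 for 12 h to 48 h, 20 for 48 h to 6 d and 0 by limma for 4 h to 12 h, where 2933 probes had an unadjusted p under 0.05. Adding a 2-fold minimum left 248, 565, 819, 974, 1228, 1272 and 1857 probes at the 7 times in order and 549, 174, 1101 and 140 in the 4 intervals. Leaving out a replicate set or an array gave 366 to 833 at 1 h, 1676 to 2357 at 2 h, 2944 to 4537 at 3 h, 3485 to 5138 at 4 h, 4194 to 6590 at 12 h and 3283 to 5351 at 48 h. For the intervals the ranges were 479 to 1850, 13 to 1024, 1409 to 3151 and 64 to 369, and for the F test 4406 to 8930. A 2-fold minimum lowers counts by construction. Fewer arrays lowered most counts, but 48 h to 6 d rose to 369 without 6 d replicate 1, the F test to 8930 without 3 h replicate 1 and 4 h to 12 h to 1024 without 4 h replicate 3, while 4 h to 12 h reached 13 without set 1 and 13 without set 2. The cause was not tested for these or for the shifts under quantile normalization. Without intensities, how dim probes limit these results is unknown.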

Other observations

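The tests on replicate set 1 and on the time labels were chosen after their results were seen in part; the regroupings within replicate sets were added later still, and the other splits and regroupings of arrays were planned beforehand. The reproducible spread of the log ratios, estimated from the covariances between sets, was smaller in replicate set 1 than in sets 2 and 3 at 2 h, 3 h, 4 h, 12 h and 6 d, but larger than in set 3 at 1 h (0.0916 against 0.0754) and about that of set 2 at 48 h (0.155 against 0.153). In set 1 it was 0.963 of that of the other sets at 1 h (95% bootstrap interval over probes 0.934 to 0.992), 0.895 at 2 h, 0.663 at 3 h, 0.62 at 12 h (0.608 to 0.631), 0.837 at 48 h and 0.729 at 6 d. Whether 1 compression factor acted on all arrays of set 1 stays open: the largest fraction was 1.55 times the smallest, but the same ratio was 2.01 for set 2 and 2.04 for set 3, so single arrays vary by more, and the bootstrap over probes leaves that variation out. A set that ran behind in time is a candidate explanation that also stays open. Of the 7 arrays of set 1, 1, the 3 h array, correlated best with an earlier time of the other sets. The 3 h arrays of sets 2 and 3 correlated best with 4 h, and the 4 h array of set 3 with 12 h. A delay of set 1 would give these directions, but all other arrays were nearest to their own time. The wide spacing after 4 h hides a short delay. A lower share of responding cells in set 1 may also contribute and was not tested.

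The order of the arrays in time bears on the labels that differ between fields. Over the 21 pairs of times, similarity between arrays of different sets fell with distance in the order of the titles with a Spearman rho of -0.902, stronger than in any other of the 2520 distinct orders. In the order of the descriptions rho was -0.353, reached or passed by 222 orders. If expression changes gradually, the values argue against the times in the description field, under which cells at 1 h and 2 h would share almost nothing (mean r -0.0429 between sets). Matched with the time means of the other sets, 17 of 21 arrays were nearest to their own titled time and 4 to an adjacent one, which for 3 of these is the time in their description. The 6 d array titled replicate 2, which its description numbers 3, correlated with the arrays of set 2 (mean r 0.38 after removal of time means) and hardly with those of set 3 (mean r -0.022).

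How many probes other groupings of the same arrays would call was examined. For the F test over 7 times, 1 of 100 regroupings of the 21 arrays, the real one, reached 8693 probes and the highest other reached 1489. This argues against chance there, as far as 100 regroupings can show. Those regroupings ignored the replicate sets. With times regrouped only within sets, the highest other of 100 reached 12, and with the replicate block 1206 against a real count of 11011. For each time against the control, only 4 sign patterns of 3 arrays exist, and for each interval only 10 splits, too few for a share under 0.05. The real pattern gave the most calls in each case (1 of 4 and 1 of 10). At 1 h, 2 h, 3 h, 4 h and 48 h the highest other pattern gave 0 calls by limma, at 12 h it gave 1 and at 6 d 5. For 48 h to 6 d the highest other split gave 5 and for the other intervals 0. Among the 4 splits of an interval that part all 3 pairs, the other splits gave 0.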
